A study of Myxococcus xanthus with 8 samples.

How the data were processed

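RNA of 4 strains of the soil bacterium Myxococcus xanthus was compared on 8 arrays with 2 colours each: the wild type DK1622, MR1543 with a Tn5-lac insertion in ddvA, MR1544 with that insertion and a carD deletion, and MR1545 with that insertion and a carG deletion. The labels give vegetative cells at an OD600 of 0.9, while the growth protocol gives an OD550 of 1.0. The arrays form 4 pairs of strains with 2 arrays each and the dyes exchanged between them, so that every strain lies on 4 arrays. All arrays came from 1 slide and 1 scan. On it the arrays with MR1544 and those with MR1545 lay in different columns, and each column held its 2 pairs in both dye orientations, so a column effect that adds to the log ratio cancels. The design text gives at least 3 biological replicates per condition but does not say which cultures went on which array, or whether the arrays of a dye swap share RNA extracts. The p-values therefore measure the spread between arrays.

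Per the file headers, the authors scanned the arrays and extracted the spots with Agilent Feature Extraction 10.7.3.1. The deposited scanner files hold median spot and background values as intensity on a linear scale for the green (Cy3) and red (Cy5) channel, together with processed intensity after the extraction software's own background subtraction and dye normalization. The deposited log10 ratio of red over green equals the log10 of the ratio of processed values, within 0.001, for 98.3% of spots. The deposited log2 value table runs as Cy5 over Cy3 by comparison with the scanner values, with correlations of 0.9895 to 0.9957 across genes. Its background correction and normalization are not stated in the sources used here. Its 8 column medians, in the order of the arrays of MR1544 and DK1622, MR1544 and MR1543, MR1545 and MR1543, and MR1545 and DK1622, were 0.005119, -0.00951, -0.006739, 0.004713, 0.006297, -0.02022, -0.002621 and -0.005926.

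From the intensities, the background was corrected by normexp with an offset of 50, the log2 ratio was normalized by loess within each array, and spots of a probe were averaged, with limma 3.58.1 in R 4.3.3. The plan named mean spot signals, but the median signals in the files were used. Control spots and spots marked as outliers were left out, and no spot was saturated. The arrays hold 7299 gene targets with 1 probe each. By coordinates on the chromosome of assembly ASM1268v1, 4725 targets matched a gene at both ends, 2278 at the 3' end and 21 by an overlap of at least 80%. The other 275 were left without a locus tag, and 824 targets have a gene symbol. Of the targets, 117 lacked a value on 1 array or more. Median signals ran from 379 to 721 in Cy3 and from 394 to 728 in Cy5, against median backgrounds of 19 to 21 and 64 to 69, and 92.5% to 100% of spots per channel were well above background. The number of arrays limits the precision.

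The comparison model, fixed before the data were examined, was a linear model over all 8 arrays with a term per strain and a gene-wise dye term (4 residual degrees of freedom), followed by empirical Bayes moderation and Benjamini-Hochberg adjustment within each of the 6 strain comparisons at a threshold of 0.05. MR1543 and DK1622 share no array, nor do MR1544 and MR1545, so these differences are indirect. Standard errors were taken by refitting with another baseline strain, because the approximate contrast calculation is inexact for genes with missing arrays. That change was made after a first look at the counts and moved them slightly. All adjusted p-values of genes are limma's.

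A feature of the layout was noticed only after the values had been seen. The 8 arrays fall into 2 loops of 4 that share no combination of strain and dye. The first loop holds DK1622 and MR1543 in Cy5 and the second holds them in Cy3. A fit with 1 value per strain within each loop and the loops as replicates (2 residual degrees of freedom) was therefore added as an alternative, and its counts are given beside the others. Within a loop, MR1543 minus DK1622 and MR1544 minus MR1545 are free of an additive dye effect, so loop values of single genes and runs are given for those comparisons.

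Genes were named by a rule fixed in advance: per comparison, the 10 largest rises and falls past the threshold whose estimates by both paths round the loop had the sign of the fit, up to 4 members of each gene list with the largest change, and the 10 longest runs of at least 3 neighbouring loci past the threshold in 1 direction. The rule also named carD, carG, ddvA and ddvS, but the tables used here hold no such symbols, so MXAN_5622, MXAN_5623, MXAN_7288 and MXAN_7289 were followed through all comparisons after their values were seen. Of 18 gene lists fixed for a set test, 10 had at least 5 members. The lists had been defined by product descriptions, which the tables used here do not give, so they were recast as symbols before gene values were seen. The pattern for aminoacyl-tRNA synthetases was narrowed afterwards to leave out other enzymes. No set test was made for sigma factors (2 members), carotenoid genes (3), development (2) or polyketide and peptide synthetases (0), nor for anti-sigma factors, serine/threonine kinases, sigma-54 dependent regulators and two-component signalling, which could not be formed from symbols. Lists were tested with camera at a preset correlation of 0.01, adjusted over the lists of a comparison, and again with the correlation estimated from the data.

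The results were computed again under 22 settings fixed in advance: 3 other treatments of the intensities, median centring, Aquantile normalization between arrays (which leaves the ratios as they are), the deposited log2 table, a filter on dim probes, 3 other treatments of dye and array pairs, another prior, a minimum absolute log2 change of 1, each array left out, and each path round the loop. A probe-level alternative was not run, because nearly every locus has 1 probe (40 loci have more), and 2 settings were added after the data had been seen, the loops as replicates and the replicate number as a term of the model. In simulated data for MR1543 against DK1622 with the noise of the 7299 real genes, the fit recovered 44% of changes of 0.5 on the log2 scale, 94% of changes of 1 and 100% of changes of 2, with 11 false calls. That simulation draws independent array noise and so leaves out shared labelled samples. The correlation of the deletion effects was set against 20 simulated data sets of unchanged strains, with array noise and noise shared by arrays that hold the same strain and dye. The plan set the overlaps against these sets too, but so few genes were called in them that hardly any overlap could arise, and that comparison was left out. The overlap of independent lists and Fisher's exact test, planned beside it, were left out too, because the lists share the MR1543 samples. The shared noise was first averaged over the strains. After that output had been seen, it was taken separately for DK1622 and MR1543 (0.316 of the array variance) and for MR1544 and MR1545 (0), which raised the simulated correlation of the deletion effects. DK1622 and MR1543 share 1 value, so noise that lies mainly in MR1543 is not represented. The 0 is a floor, because the SD of the loop difference in MR1544 minus MR1545 was 0.248. That lies below the 0.381 expected from array noise alone, so both shares are rough.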

Results

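Expression was measured in vegetative cells of Myxococcus xanthus by hybridising pairs of strains to 8 arrays covering 7299 gene targets, with 4 arrays per strain. The series addresses the genes controlled by an ECF sigma factor, one of the alternative sigma factors that answer signals at the cell envelope, and how they depend on the proteins CarD and CarG. MR1543 carries an insertion in ddvA, and MR1544 and MR1545 carry it with a deletion of carD or of carG. Values are log2 fold changes ± SE from 8 arrays, and coordinates are those of the chromosome in assembly ASM1268v1. Median signals were 379 to 721 in Cy3 and 394 to 728 in Cy5.

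MXAN_5622, a target of 951 bp at 6986642 to 6987592, fell by 5.12 ± 0.20 on the log2 scale in MR1544 against MR1543 (adjusted p = 0.00015), and its difference in MR1545 was -0.03 ± 0.20 (adjusted p = 0.94). The neighbouring MXAN_5623, a target of 513 bp at 6987651 to 6988163, fell by 3.64 ± 0.15 in MR1545 against MR1543 (adjusted p = 0.00023), and its difference in MR1544 was 0.44 ± 0.15 (adjusted p = 0.1). Each was the largest fall of all genes in its deletion strain against MR1543. The tables used here give neither locus a symbol, and both were singled out after their values were seen.

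The first comparison set MR1543 against DK1622 and asks which genes respond to the ddvA insertion. The rises were led by a chromosomal block of 17 neighbouring targets from MXAN_7276 to MXAN_7292, at 8888371 to 8909309, with a median log2 change of 3.78. MXAN_7291 rose by 8.46 ± 0.32, MXAN_7290 by 7.89 ± 0.21 and MXAN_7289 by 7.55 ± 0.25, with adjusted p of 5.1e-05, 1.9e-05 and 3.2e-05. The adjacent MXAN_7288 rose less, by 2.91 ± 0.17 (adjusted p = 0.00029). In the same block, the CRISPR-Cas genes cmr4 (4.12 ± 0.45), cmr6 (3.57 ± 0.49), cas10 (3.42 ± 0.46) and cas6 (MXAN_7276, 3.36 ± 0.43) rose with adjusted p of 0.0044, 0.014, 0.013 and 0.011. MXAN_7284 was not well above background in DK1622 and was at least 8.81-fold higher in MR1543, a bound taken per channel after loess and Aquantile normalization between arrays (adjusted p = 0.014). The rise of this block differed between the loops, with medians of 4.85 in the first and 2.78 in the second, and 10 of its 17 targets passed the test with the loops as replicates. Among the 7 that did not were cmr6 (adjusted p = 0.067), cas10 (0.071), cas6 (0.053) and MXAN_7284 (0.051).

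**Figure D1:**
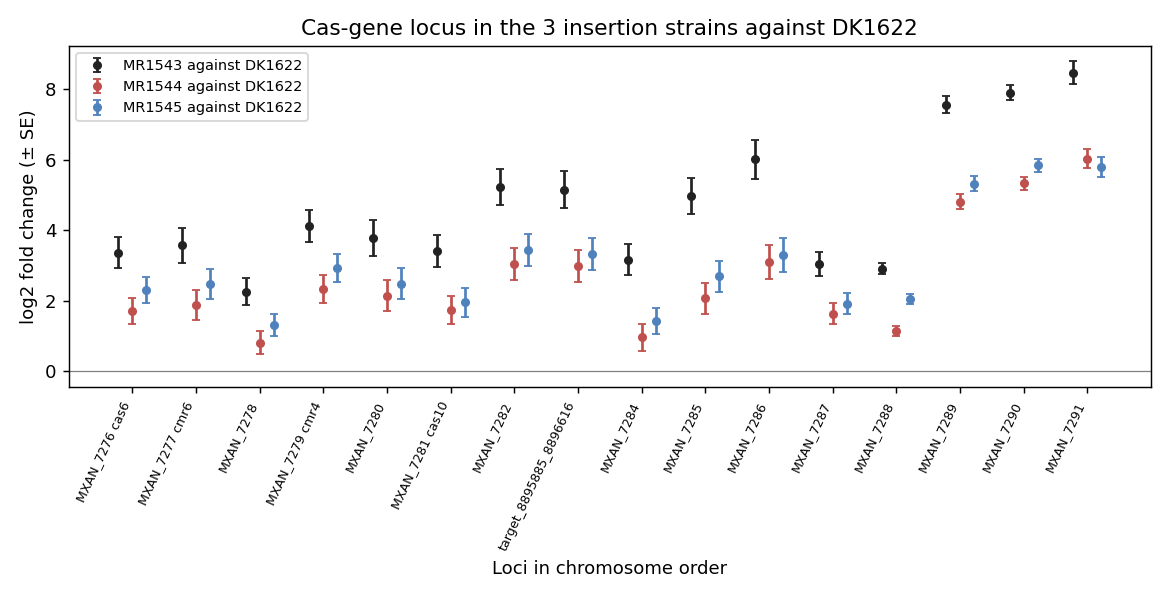
Log2 fold change against DK1622 (y axis, points with SE bars) of 16 neighbouring targets in chromosome order (x axis) for MR1543, MR1544 and MR1545. MXAN_7291 stands at 8.46 in MR1543, 6.03 in MR1544 and 5.79 in MR1545.

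Falls in MR1543 were led by genes for the iron-chelating siderophore myxochelin. All 5 measured members of the iron and TonB list fell, both over all genes and adjusted over the list alone, including mxcK (-3.81 ± 0.25), mxcG (-3.72 ± 0.21), mxcL (-3.58 ± 0.29) and dhbC (-3.46 ± 0.19), whose adjusted p were 0.00047, 0.00029, 0.0013 and 0.00029. These 4 belong to a run of 10 falling loci from MXAN_3639 to MXAN_3648, at 4337073 to 4353626, with medians of -3.42 in the first loop and -3.6 in the second. The fit with the loops as replicates called 8 of the 10, these 4 among them. The fifth list member, mxcH (-2.55 ± 0.18, adjusted p = 0.00078), lies in a separate run of 5 falling loci from MXAN_1686 to MXAN_1690, of which that fit called 3, with mxcH at an adjusted p of 0.015. MXAN_6911 fell by 3.26 ± 0.12, MXAN_6640 by 3.17 ± 0.14 and rpsD (MXAN_6805), for a ribosomal protein, by 3.06 ± 0.18. The fatty acid gene fabD (MXAN_3942) rose by 1.02 ± 0.14 (adjusted p = 0.013), a call lost with the loops as replicates (0.06), and the other 17 members of its list did not pass.

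Of 54 ribosomal protein genes, 5 rose, among them rpsJ (0.60 ± 0.09) and rplE (0.58 ± 0.09), and rpsD fell. None of the 5 rises kept its call with the loops as replicates, where the adjusted p were 0.054 for rpsJ and 0.083 for rplE, while rpsD kept it. Adjusted over the list alone, 33 rose and 1 fell. Of 15 CRISPR-Cas genes, 4 rose, and 7 did when adjusted over the list alone. With the preset correlation, the camera test called CRISPR-Cas (adjusted p = 1.29e-09) and ribosomal proteins (1.82e-18) higher and iron and TonB transport (4.92e-13) lower. It also called the 23 aminoacyl-tRNA synthetases higher (0.00103), of which none passed singly. None of these calls held with an estimated correlation, where the adjusted p were 0.274 for CRISPR-Cas, 0.274 for ribosomal proteins, 0.203 for iron and 0.412 for the synthetases. No member of the lists for respiration, chaperones, motility, DNA repair, mobile elements, sigma factors, carotenoids or development passed the test over all genes, and 3 DNA repair genes were lower when adjusted over the list alone.

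In all, 59 genes were higher and 87 lower among 7292 tested. With the 2 loops as replicates, 26 were higher and 64 lower, of which 19 and 58 were also called with all 8 arrays. The dye-swap arrays with MR1543 correlated across genes at 0.227 with MR1544 and 0.276 with MR1545, against 0.782 and 0.813 for those strains with DK1622. Without the array MR1545 and MR1543 replicate 1 only 16 were higher, and without MR1545 and DK1622 replicate 1 only 55 were lower.

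The second comparison set MR1544 against MR1543 and asks what the carD deletion changes in the insertion strain. MXAN_7212 fell by 3.08 ± 0.25, MXAN_1892 by 3.07 ± 0.34, MXAN_1810 by 2.80 ± 0.22, MXAN_2938 by 2.69 ± 0.17 and MXAN_7043 by 2.64 ± 0.11. The longest run of falls held 12 targets from MXAN_7281 to MXAN_7292, with a median of -2.19, and MXAN_7289 in it fell by 2.75 ± 0.21. Only 4 of the 12 were called with the loops as replicates. Of the 15 CRISPR-Cas genes 3 fell, including cmr4 (-1.79 ± 0.39) and cas6 (-1.65 ± 0.37), and 4 did when adjusted over the list alone. The calls of cmr4 and cas6 (adjusted p = 0.14 for each) and cas10 (0.17) were lost with the loops as replicates. The set test gave an adjusted p of 0.00252, which was lost with an estimated correlation (adjusted p = 0.6). Among rises were MXAN_6451 (2.07 ± 0.17) and MXAN_5266 (1.79 ± 0.12).

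Both development genes rose, mrpC, a regulator of fruiting, by 1.03 ± 0.18 and spoVG by 0.73 ± 0.11. The sigma factor gene rpoD fell by 0.59 ± 0.11, and uvrA (MXAN_2388), for nucleotide excision repair, by 0.88 ± 0.13. Of these, mrpC (adjusted p = 0.089), spoVG (0.057) and uvrA (0.068) lost their call with the loops as replicates. Of the other lists, 3 ribosomal protein genes and 1 motility gene rose, and 3 chaperone or protease genes, 2 DNA repair genes and 1 respiration gene fell. None of these calls was kept with the loops as replicates. Of the 5 iron and TonB genes, 4 were lower when adjusted over the list alone and none over all genes. In all, 278 genes were higher and 457 lower. With the loops as replicates 71 were higher and 200 lower, and without the array MR1544 and MR1543 replicate 2 there were 73 and 202.

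The third comparison set MR1545 against MR1543 and asks the same of carG. MXAN_7043 fell by 2.61 ± 0.11, MXAN_2938 by 2.58 ± 0.17, MXAN_2271 by 2.37 ± 0.17, MXAN_3810 by 2.34 ± 0.18, MXAN_2232 by 2.33 ± 0.13 and MXAN_3170 by 2.32 ± 0.11. In the block raised by the insertion, 5 neighbouring targets from MXAN_7288 to MXAN_7292 fell with a median of -2.06, and so did 3 from MXAN_7284 to MXAN_7286, a run outside the naming rule that was singled out after its values were seen, with a median of -2.28. Of the 5 and the 3, the fit with the loops as replicates called 3 and 0. None of the 15 CRISPR-Cas genes passed, and cas10 stood at -1.47 ± 0.40 (adjusted p = 0.084). MXAN_6998 rose by 2.10 ± 0.23, MXAN_2399 by 2.29 ± 0.22 and MXAN_2840 by 2.10 ± 0.14. Both development genes rose, spoVG by 1.37 ± 0.11 and mrpC by 1.25 ± 0.18, while rpoD fell by 0.68 ± 0.11 and clpA, for a protease subunit, by 0.82 ± 0.11. The call of mrpC was lost with the loops as replicates (adjusted p = 0.066).

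Ribosomal proteins were called lower as a set (adjusted p = 3.56e-05, lost at 0.866 with an estimated correlation), with 3 members higher and 1 lower, none of them called with the loops as replicates. Of the other lists, 2 chaperone or protease genes, 2 DNA repair genes and 1 aminoacyl-tRNA synthetase gene fell, and of these only 1 chaperone or protease gene, clpA, kept its call with the loops as replicates. In all, 152 genes were higher and 308 lower. With the loops as replicates 54 were higher and 151 lower, and without the array MR1545 and MR1543 replicate 1 there were 25 and 77.

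Of the 59 genes higher in MR1543, 19 were lower in MR1544 and 13 in MR1545 against MR1543, and 12 were lower in both. The comparisons share the MR1543 samples with opposite signs, so noise in those samples can raise such an overlap. By how much was not settled. Across all genes, MR1543 against DK1622 and MR1544 against MR1543 correlated with r = -0.282, nearer to 0 than the -0.622 of simulated unchanged strains. Their covariance of -0.0529 lay further from 0 than the simulated -0.0167. The r and the covariance thus point in different directions, so r alone does not show a reversal weaker than noise. The simulation gave MR1543 and DK1622 equal shared noise, and more noise in MR1543 would move its r and covariance further from 0. With the first effect taken from 1 loop and the second from the other, which still share an estimated dye term, r was 0.046 and -0.301 for MR1544 and -0.099 and -0.186 for MR1545. Of the 59, only 29 in MR1544 and 37 in MR1545 lay below MR1543, and their median log2 rise over DK1622 was 0.89 in MR1543, 1.09 in MR1544 and 0.94 in MR1545. Against DK1622, 52 of the 59 were still higher in MR1544 and 51 in MR1545. The 59 were chosen against the same DK1622 samples, whose noise can raise both counts. MXAN_7289, for example, was 4.80 ± 0.21 above DK1622 in MR1544 and 5.31 ± 0.21 in MR1545. With the loops as replicates the overlaps were 6 and 7 genes, and without the array MR1545 and MR1543 replicate 1 they were 6 and 2. Of the 87 genes lower in MR1543, 21 were higher in MR1545 and 2 in MR1544 against MR1543.

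The carD and carG effects correlated across genes, which are not independent replicates, with r = 0.776 and a covariance of 0.11. In simulated unchanged strains, which share MR1543, r was 0.525 and the covariance 0.0115. Equal shared noise was simulated for MR1543 and DK1622, and more noise in MR1543 would raise this r. With the carD effect from 1 loop and the carG effect from the other, which still share an estimated dye term, r was 0.769 and 0.482. The correlation across genes of carD and carG effects was 0.642 by the direct arrays and -0.052 by the second path, in which both effects hold the pairs with DK1622 with opposite signs. Of the falls, 260 genes were shared, a count that the shared MR1543 samples raise.

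**Figure D2:**
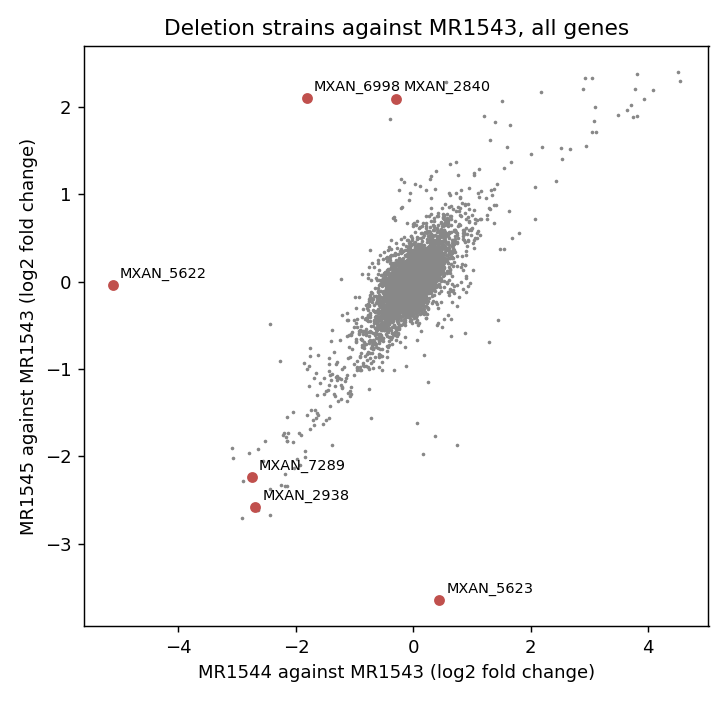
Log2 fold change of each gene in MR1545 against MR1543 (y axis) and in MR1544 against MR1543 (x axis), with 6 named loci in red. MXAN_5622 lies at -5.12 on the x axis and MXAN_5623 at -3.64 on the y axis.

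The test of MR1544 against MR1545, which share no array, asks whether the deletions differ. Apart from MXAN_5622 and MXAN_5623, MXAN_6998 was lower in MR1544 by 3.91 ± 0.26 on the log2 scale and MXAN_2840 lower by 2.39 ± 0.16, both with adjusted p = 0.002. A run of 6 loci from MXAN_0046 to MXAN_0051 was lower with a median of -1.08, and MXAN_4291 was higher by 1.46 ± 0.17. The fit with the loops as replicates called only 1 of the 6, and not MXAN_4291 (adjusted p = 0.14). In all 9 genes were higher and 14 lower, and with the loops as replicates 3 and 4. Without the array MR1545 and MR1543 replicate 1 there were 1 and 4.

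Against DK1622, MR1544 and MR1545 had the highest counts of called genes. The comparison of MR1543 with DK1622 is indirect and less precise, so the counts do not rank the size of the changes. Its median SE was 0.113, against 0.0975 for MR1544 and 0.0974 for MR1545. In MR1544, 962 genes were higher and 1215 lower, and in MR1545 464 and 621. With the loops as replicates the counts were 558 and 678 in MR1544 and 250 and 343 in MR1545. Without the array MR1544 and DK1622 replicate 1 there were 399 and 600 in MR1544, and without MR1545 and DK1622 replicate 2 there were 137 and 267 in MR1545. The run from MXAN_3639 to MXAN_3648 fell in both, with medians of -3.89 and -3.44. In MR1544 a run of 16 loci from MXAN_3299 to MXAN_3314, which holds 14 named ribosomal protein genes, rose with a median of 0.44. A run of 14 loci from MXAN_4288 to MXAN_4301 rose there with a median of 1.25, and in MR1545 20 loci from MXAN_3931 to MXAN_3950, including fabD and lspA, rose with a median of 0.91. Of these 3 runs, 11, 14 and 13 loci were also called with the loops as replicates, lspA not among them (adjusted p = 0.13).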

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

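The tests of explanations in this part were chosen after the results were seen, except the channel swaps. The carD and carG effects, each against MR1543, differed by the test of MR1544 against MR1545 for 23 targets. Lower in MR1544 than in MR1545 were MXAN_5622 (-5.09), MXAN_6998 (-3.91), MXAN_2840 (-2.39), MXAN_7371 (-1.96), MXAN_0047 (-1.38), MXAN_0050 (-1.30), MXAN_7464 (-1.30), MXAN_0048 (-1.08), MXAN_0046 (-1.07), MXAN_0049 (-1.06), a probe of MXAN_4325 (-1.05), MXAN_0051 (-1.01), MXAN_4323 (-0.79) and MXAN_2839 (-0.68) on the log2 scale. Higher were MXAN_5623 (4.08), MXAN_6103 (1.68), MXAN_4291 (1.46), MXAN_0228 (1.27), MXAN_5266 (1.23), MXAN_1697 (1.18), MXAN_5047 (0.90), MXAN_5621 (0.89) and MXAN_1696 (0.75). With the loops as replicates only MXAN_5622, MXAN_6998, MXAN_2840, MXAN_0047, MXAN_5623 and MXAN_0228 kept their call. MXAN_6998 differed in direction, at -1.81 in MR1544 and 2.10 in MR1545 against MR1543.

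Turning the channels of single arrays at random tested chance, with 100 of the 128 distinct assignments drawn. As many genes were called in 3 of 100 draws for MR1543 against DK1622 and in 2 of 100 for MR1544 against MR1545, the real assignment included, and in 1 of 100 for each other comparison. Each share lies below the bound of 0.05 set in advance. Turning an array also turns true strain differences into spread, which lowers the counts of other draws. Their median was 0 in every comparison. The real assignment can therefore rank high by construction, so chance in a single comparison is not excluded. Arrays with the same strain and dye share noise, put at 0.316 of the array variance for DK1622 and MR1543, which turning an array breaks, so chance in the labelled samples is not excluded either. The real counts were 146, 735, 460, 2177, 1085 and 23, in the order of the report's strain pairs MR1543 and DK1622, MR1544 and MR1543, MR1545 and MR1543, MR1544 and DK1622, MR1545 and DK1622, and MR1544 and MR1545. The highest others were 641, 156, 163, 1638, 208 and 978. The 978 came from turning all 4 arrays with MR1545 and the 641 from turning 3 arrays with MR1543. Turning whole pairs of arrays carries true differences between strains into other comparisons, so high counts can arise by construction, which makes this a weak test. The 1638 and the 208 each came from turning 1 array, which whole pairs do not explain.

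The rise of MXAN_7289 to MXAN_7291 was kept in part in both deletion strains, at 14.8% to 18.5% of the MR1543 level in MR1544 and 15.7% to 24.0% in MR1545. MR1543 RNA carried into those samples would bring the deleted genes along. The upper 95% bound of MXAN_5622 in MR1544 was 3.96% of its MR1543 level and that of MXAN_5623 in MR1545 was 10.2%, below every share of the 3 genes. The loci were picked as the largest falls, so a share below that of the 3 genes was given in advance, and the bounds do not allow for the picking. Only the size of the gap was not given in advance. That gap argues against carry-over as the whole cause, if these loci are the deleted genes. Expression independent of CarD and CarG stays open and was not tested.

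The run from MXAN_3639 to MXAN_3648 was lower in MR1543, MR1544 and MR1545. If 1 DK1622 labelled sample stood apart, the fall would show in 1 loop, and 8 of its 10 genes fell by over 1 on the log2 scale in both loops, short of the 9 first set as the bound. The others were MXAN_3639, at -1 and -1.55 in the loops, and MXAN_3648, at -0.57 and -0.81. The medians of the run, looked at after that bound was missed, were -3.42 and -3.6, which argues against 1 odd labelled sample as the cause for the run as a whole. A DK1622 culture that supplied both labelled samples cannot be told apart, since the loops' medians differ by only 0.17. All 3 strains with the insertion showed the fall, so the insertion and the antibiotic that the growth protocol adds where required cannot be told apart either.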

How the results depend on the processing

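The settings with the loops as replicates and with a replicate block were chosen after seeing the data. None of the 469 values of named genes past the threshold (466 under the filter on dim probes) changed sign, but many lost their call: 329 by the second path, 202 with the minimum change, 155 with the loops as replicates, 110 by the first path, 102 without a dye term, 93 with dye-swap arrays averaged, 20 with a replicate block, 64 to 123 with an array left out, and 0 to 17 under the others. For many settings the sign could not change. The minimum change and the other prior leave the estimates as they are. So do the loops as replicates, no dye term and averaged dye swaps for genes with all arrays. The largest rises and falls were named only where both paths had the sign of the fit, so neither path could reverse them. No background correction, a normexp offset of 0, the processed signals, median centring, the deposited log2 table, the filter on dim probes (6941 genes left), the array pair as a random block and the robust prior left every count of genes within 1.5 times. Aquantile normalization between arrays leaves ratios as they are by construction and so tested nothing. Some counts moved further under the settings below, and where no construction is named the cause was not tested. Without a dye term, higher genes numbered 33 in MR1543 against DK1622, 123 in MR1544 against MR1543, 75 in MR1545 against MR1543, 589 in MR1544 against DK1622 and 258 in MR1545 against DK1622. The lower genes numbered 262 in MR1544 against MR1543, 205 in MR1545 against MR1543, 704 in MR1544 against DK1622 and 413 in MR1545 against DK1622. The genes higher in MR1543 and lower in a deletion strain then numbered 12 for MR1544 against MR1543 and 8 for MR1545 against MR1543. With dye-swap arrays averaged, which leaves 1 residual degree of freedom, higher genes numbered 34 in MR1543 against DK1622, 156 in MR1544 against MR1543, 76 in MR1545 against MR1543, 567 in MR1544 against DK1622, 261 in MR1545 against DK1622 and 4 in MR1544 against MR1545. The lower genes numbered 280 in MR1544 against MR1543, 167 in MR1545 against MR1543, 769 in MR1544 against DK1622, 355 in MR1545 against DK1622 and 6 in MR1544 against MR1545. With an absolute log2 change of at least 1, a stricter rule by construction, higher genes numbered 27 in MR1543 against DK1622, 39 in MR1544 against MR1543, 29 in MR1545 against MR1543, 132 in MR1544 against DK1622 and 78 in MR1545 against DK1622. The lower genes numbered 108 in MR1544 against MR1543, 84 in MR1545 against MR1543, 199 in MR1544 against DK1622 and 143 in MR1545 against DK1622. By the first path alone, which uses fewer arrays, higher genes numbered 14 in MR1543 against DK1622, 93 in MR1544 against MR1543 and 1 in MR1544 against MR1545. The lower genes numbered 45 in MR1543 against DK1622, 271 in MR1544 against MR1543 and 1 in MR1544 against MR1545. The genes higher in MR1543 and lower in a deletion strain then numbered 8 for MR1544 against MR1543 and 4 for MR1545 against MR1543. By the second path alone, higher genes numbered 24 in MR1543 against DK1622, 15 in MR1544 against MR1543, 0 in MR1545 against MR1543, 192 in MR1544 against DK1622, 71 in MR1545 against DK1622 and 1 in MR1544 against MR1545. The lower genes numbered 53 in MR1543 against DK1622, 72 in MR1544 against MR1543, 10 in MR1545 against MR1543, 314 in MR1544 against DK1622, 180 in MR1545 against DK1622 and 1 in MR1544 against MR1545. The genes higher in MR1543 and lower in a deletion strain then numbered 5 for MR1544 against MR1543 and 0 for MR1545 against MR1543. With the loops as replicates, higher genes numbered 26 in MR1543 against DK1622, 71 in MR1544 against MR1543, 54 in MR1545 against MR1543, 558 in MR1544 against DK1622, 250 in MR1545 against DK1622 and 3 in MR1544 against MR1545. The lower genes numbered 200 in MR1544 against MR1543, 151 in MR1545 against MR1543, 678 in MR1544 against DK1622, 343 in MR1545 against DK1622 and 4 in MR1544 against MR1545. The genes higher in MR1543 and lower in a deletion strain then numbered 6 for MR1544 against MR1543 and 7 for MR1545 against MR1543. With the replicate number as a term of the model, a replicate block whose numbers only follow the order of deposition, higher genes numbered 69 in MR1543 against DK1622, 316 in MR1544 against MR1543, 172 in MR1545 against MR1543, 1069 in MR1544 against DK1622, 489 in MR1545 against DK1622 and 4 in MR1544 against MR1545, and lower genes 103 in MR1543 against DK1622, 483 in MR1544 against MR1543, 338 in MR1545 against MR1543, 1262 in MR1544 against DK1622, 655 in MR1545 against DK1622 and 9 in MR1544 against MR1545. The overlaps were 21 and 22 and the correlation 0.776. With this term, only the counts in MR1544 against MR1545 and the overlap of 22 moved by over 1.5 times. The correlation across genes of carD and carG effects was 0.642 by the first path and turned to -0.052 by the second, in which both effects hold the pairs with DK1622 with opposite signs by construction. With each array left out in turn, the counts ran from 16 to 73 genes higher in MR1543 against DK1622, 55 to 101 genes lower in MR1543 against DK1622, 73 to 256 genes higher in MR1544 against MR1543, 202 to 444 genes lower in MR1544 against MR1543, 25 to 182 genes higher in MR1545 against MR1543, 77 to 304 genes lower in MR1545 against MR1543, 399 to 1172 genes higher in MR1544 against DK1622, 600 to 1408 genes lower in MR1544 against DK1622, 137 to 479 genes higher in MR1545 against DK1622, 267 to 618 genes lower in MR1545 against DK1622, 1 to 23 genes higher in MR1544 against MR1545 and 4 to 18 genes lower in MR1544 against MR1545. Each of the 8 arrays moved a count by over 1.5 times when left out. The overlaps then ran from 6 to 24 for MR1544 and from 2 to 22 for MR1545, and the correlation from 0.614 to 0.815. With an estimated correlation between genes, the adjusted p of the lists that lost their call were 0.274 for CRISPR-Cas, 0.274 for ribosomal proteins, 0.412 for aminoacyl-tRNA synthetases and 0.203 for iron and TonB transport in MR1543 against DK1622, 0.6 for CRISPR-Cas in MR1544 against MR1543 and 0.866 for ribosomal proteins in MR1545 against MR1543. The arrays limit dim genes, and MXAN_7284 has only a bound in DK1622.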

Other observations

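All tests in this part were chosen after the results were seen. A group of 40 genes differed by over 2 on the log2 scale between the loops in MR1543 minus DK1622, and 36 of them were lower in the second loop. MXAN_3966 stood at -1.89 in the first loop and -7.65 in the second, nrfD at -0.43 and -6.06, hemN, for a step of haem synthesis without oxygen, at -1.80 and -6.49, and ccoG at 0.63 and -3.59. Of the 40 genes, 4 were called in MR1543 against DK1622. They were MXAN_7280, MXAN_7282, MXAN_7286 and the target at 8895885 to 8896616. All 4 lie in the raised block from MXAN_7276 to MXAN_7292, so the loop difference reaches that block. MXAN_7286, for example, stood at 7.05 in the first loop and 4.97 in the second.

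Across all genes the dye-swap arrays correlated at 0.227 for MR1544 and MR1543 and 0.276 for MR1545 and MR1543, against 0.782 and 0.813 for the pairs with DK1622. A dye bias that changes between arrays would also separate the loops in MR1544 minus MR1545. There the median absolute difference over all genes was 0.115, against 0.212 in MR1543 minus DK1622, and 6 genes differed by over 2. For the 40 genes the medians were 0.87 and 3.91, but these genes were chosen for the second value, and the first lies above that of all genes, so such a bias stays open. A single poor array would show by 1 route only, and the routes by MR1544 and by MR1545, which share no array, had the same sign for 100% of the 40 genes. These genes were chosen on the mean of the routes, which favours equal signs. Over all genes the loop differences by the routes correlated at 0.484. Against the mean of the deletion strains, the loop difference was 12.7 times larger for MR1543 than for DK1622. The medians of the 40 genes were 4.15 and 0.33. An additive dye effect enters both differences alike, so samples of DK1622 as the source would need dye effects as large as the MR1543 values. Their lower quartile was 1.94, while 99% of the other genes stayed below 1.51, which argues against DK1622 and points to the MR1543 samples of the loops as a candidate explanation. Whether culture, extraction or labelling differed stays open too, since the labels do not say which cultures went on which array.

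MXAN_5622 in MR1544 and MXAN_5623 in MR1545 each ranked 1 among the falls of 7299 genes against MR1543. Against DK1622 they ranked 1 and 3. Whether MXAN_5622 is the gene deleted in MR1544 and MXAN_5623 is the gene deleted in MR1545 stays open, because the loci were picked for these falls and the tables used here hold no symbol to settle it.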
